A study of Mus musculus with 96 samples.

How the data were processed

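The study profiled whole ovaries of BALB/c mice with QuantSeq, an assay that sequences the 3′ end of each polyadenylated transcript. Mice aged 38 weeks at purchase received by mouth either vehicle (0.5% DMSO, the old controls) or 1 of 28 single compounds associated with Samul-tang, a herbal prescription, at 5 mg/kg, 5 times a week for 4 weeks. Young controls were 8 weeks old at purchase. All mice were given 5 IU of PMSG, a gonadotropin that drives follicle growth, and 48 h later 5 IU of hCG, which triggers ovulation. Ovaries were taken 16 to 18 h after hCG. The animals were treated in 2 batches of 14 compounds each, with 3 mice per compound and 3 old and 3 young controls in each batch, which gave 96 libraries. Old and young controls numbered 1 to 3 belong to batch 1 and those numbered 4 to 6 to batch 2. Per the labels, RNA extraction, library preparation and sequencing were done for both batches together.

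The authors deposited 1 gene table per library with expected counts, the estimated read counts per gene that RSEM writes. Their notes name FastQC 0.12.1, STAR 2.7.10b, RSEM 1.3.3 and the genome build GRCm39, and do not state the annotation release, filters or strand setting. The deposited expected counts were not normalised, and 6.0% of the values were not whole numbers, so they were rounded. The TPM and FPKM columns of the same tables divide by transcript length, which has no meaning for 3′ tags, and were not used. Each table held 78334 gene identifiers. Symbols, gene types and the last 500 bases of each transcript were joined by identifier from a GENCODE M21 annotation, which is on another genome build, so no coordinates are given. A symbol was found for 51486 identifiers, which carried 97.41% of the counts. Total counts per library ran from 7169024 to 23303207, with a median of 13118061. The libraries carry no statement on molecular identifiers, so counting error is a lower bound on their noise.

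Old and young controls were compared in edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr, a robust quasi-likelihood fit with age and batch, and Benjamini-Hochberg adjustment at 0.05. The age by batch interaction and the batch term were tested in the same 12 libraries. Each compound was compared with the 3 old controls of its own batch in 1 fit of the 45 aged libraries of that batch, so that 15 groups shared 1 estimate of the spread with 30 residual degrees of freedom. An F-test over all 14 contrasts of a batch asked whether any group differed. Compounds that differ by 1 structural feature were compared as 17 pairs, of which 15 lay within a batch. The other 2 were compared through the old controls of each batch in a fit of all 90 aged libraries. All fold changes are log2, given with a standard error, and levels are CPM, the counts scaled to library size by the cpm function of edgeR, as mean and SD.

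A set of 33 gene lists was fixed before the data were examined, with 613 entries, of which 601 matched by symbol, 10 by a synonym and 2 not at all. They were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, adjusted over the lists, or over all 924 tests of a list and a compound. Each list was also tested with the correlation estimated from the data. The age comparison was tested with fry as well. An age score was the mean log2 CPM (prior count 2) of the 100 genes with the smallest p higher in old controls minus that of the 100 lower in old controls, chosen in the controls of the other batch. Each compound's 3 scores were compared with the 42 other aged libraries of its batch by a two-sided exact permutation test over all 14190 choices. Variance between the groups was tested with 100000 permutations.

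Genes are named by a rule also fixed before the data were examined. For age, these are the 10 called genes with the largest fold in each direction that have a symbol other than a predicted name, a mean log2 CPM of at least 2 and the same sign in both batches, and up to 4 members of each list with the smallest p. For a compound, these are up to 3 genes in each direction with the largest fold whose 3 libraries all lie beyond the 3 old controls, up to 4 members of each list, and the 10 genes called for the most compounds within the same limits on symbol and level. Predicted genes called for as many compounds are given beside them. For a pair, these are up to 2 in each direction. A gene that the rule names for compounds is not reported here.

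Alternatives fixed before the data were examined were DESeq2 size factors, no filter, DESeq2 1.42.0 in place of edgeR, each replicate left out in turn, the replicate number as a block, all 96 libraries in 1 fit, each batch alone, only the 6 libraries of a comparison, the 13 other compounds of the batch as reference, adjustment over all 28 compounds together, and other gene numbers or controls for the age score. Chosen after seeing the data were a GC offset (a smooth trend over the GC content of the last 500 bases removed from each library), covariates for the share of mitochondrial ribosomal RNA and for a clock gene score, the removal of genes with a TA repeat of 9 bases or more, and fits without the benzoic and 4-hydroxybenzoic acid libraries. The clock gene score is the mean level of 10 clock output genes minus that of 5 genes of the opposite phase, centred within a batch. Its genes were listed after Per3, Dbp, Tef and Nr1d2 had been seen among the calls. Groups were reassigned at random 50 times in each batch, and the controls were split 100 ways. Simulated changes in 200 genes were used to test the fits. At 2-fold, 91% were recovered in the age comparison, 71.6% in a compound comparison of batch 1 and 73.1% in batch 2. At 1.5-fold the recovered shares were 58.2%, 31.3% and 34.3%. The simulation left out changes in genes at very low levels. It drew each count independently, with the same dispersion in all groups and no trends across libraries. The real libraries have such trends, so these shares may be too high.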

Results

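The comparisons address how the gonadotropin-stimulated ovary of aged mice differs from that of young mice, and whether any of the 28 compounds changed the aged ovary. In each batch, 3 old and 3 young controls received vehicle only.

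Between old and young controls, 743 of 17882 genes passed the threshold in edgeR, 433 higher and 310 lower in old ovaries. The count was 398 without old control 1, 468 without old control 4, 453 without young control 1 and 437 without young control 5. Of the genes named by the rule, which leaves out those with a low mean level, Gpnmb was raised most with age (log2 fold change 2.71 ± 0.38, adjusted p 0.00438), with 53.43 ± 20.14 CPM in old and 8.084 ± 4.033 CPM in young ovaries. Cpxm2 rose by 2.47 ± 0.22 (adjusted p 6.55e-05), from 5.298 ± 1.927 to 29.04 ± 6.9 CPM. The lysosomal proton pump subunit Atp6v0d2 rose by 2.05 ± 0.23 (adjusted p 0.000338) and Mmp12 by 2.29 ± 0.48 (adjusted p 0.0254). Aromatase, Cyp19a1, rose from 5.471 ± 4.579 to 17.85 ± 5.372 CPM, a change of 1.76 ± 0.42 close to the threshold (adjusted p 0.046). Sectm1a (1.75), Clec7a (1.63), Tmem178 (1.62), Acp5 (1.57) and Trpm6 (1.55) completed the 10 increases named by the rule. For each of these 10 genes all 6 old libraries lay above the young mean.

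Of the decreases named by the rule, that of Sv2c was the largest, at −2.18 ± 0.31 (adjusted p 0.00239). Slc18a2 changed by −1.61, the oocyte homeobox gene Obox2 by −1.57 ± 0.17 (adjusted p 0.000141), Derl3 by −1.56, Apoa4 by −1.53, Itih2 by −1.46, AU022751 by −1.39, Mgat4c by −1.37, Cables1 by −1.35 and the oocyte growth factor gene Bmp15 by −1.32 ± 0.2 (adjusted p 0.00176). In all 10, no old library lay above the young mean. The cell cycle inhibitor gene Cdkn2a, a member of the senescence list, rose by 1.82 ± 0.19 (adjusted p 0.000101), from 1.768 ± 0.5537 to 6.259 ± 1.007 CPM.

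**Figure D1:**
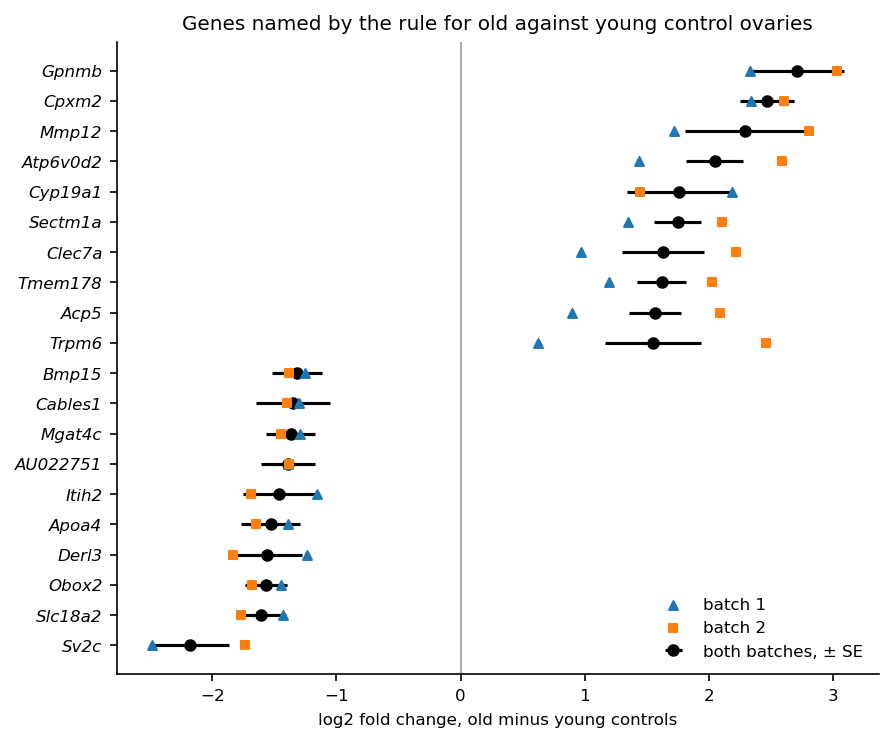
Log2 fold change of old minus young controls for the 10 genes with the largest increase and the 10 with the largest decrease among those within the limits of the naming rule (mean log2 CPM of at least 2, no predicted name), estimated over both batches (circles, bars are 1 standard error) and in each batch alone (triangles and squares, 3 against 3 libraries). Each gene changed in the same direction in both batches, as the rule for choosing them required.

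Of the oocyte transcripts, all 25 measured genes were lower in old ovaries, with a median change of −1.12, 21 passed over all genes tested and 24 when adjusted over the list alone (camera adjusted p 8.05e-45, and 0.0605 with estimated correlation). Ooep changed by −1.27, Oosp1 by −1.18, Padi6 by −1.07 and Nlrp5 by −0.97. Macrophage genes were higher in old ovaries, with a median of 0.46 and 7 of 19 genes called, 11 adjusted over the list alone (adjusted p 5.49e-11, and 0.293 with estimated correlation). Among them were Ctss (1.2), Lgals3 (1.19) and Trem2 (1.04). Genes of antigen presentation were higher as well, with 3 of 14 called and 9 adjusted over the list alone (median 0.47, adjusted p 7.22e-09, and 0.293 with estimated correlation), led by H2-DMb1 (1.27) and H2-Ab1 (1.15). T and NK cell genes had a median change of 0.97, with 4 of 10 called and 6 adjusted over the list alone (adjusted p 2.93e-05, and 0.286 with estimated correlation), including Trbc2 (1.35), Ccl5 (1.3), Il7r (1.29) and Lck (0.8). Of 6 B and plasma cell genes, 1 was called and 4 passed adjusted over the list alone (median 1.3, adjusted p 0.000924, and 0.484 with estimated correlation), and Igha rose by 2.61 ± 0.42.

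Luteal steroidogenesis was higher in old ovaries, with 4 of 19 genes called and 11 adjusted over the list alone (median 0.44, adjusted p 8.18e-08, and 0.293 with estimated correlation). Star rose by 0.94 ± 0.24, Sfrp4 by 0.84, Prlr by 0.44 and Npc1 by 0.27. Cholesterol biosynthesis genes shifted in the same direction with 0 genes called over all genes and 4 adjusted over the list alone (median 0.34, adjusted p 2.66e-05). Cell cycle genes were lower, with 0 called and 3 adjusted over the list alone (median −0.27, adjusted p 1.32e-06). For these 2 lists the adjusted p was 0.573 with estimated correlation, and 33 and 25 of 100 splits of the controls gave a camera p as small. Of the ovulation and cumulus expansion genes, Rgs2 fell by 0.83 and Cebpb rose by 0.35 (list adjusted p 0.0311, and 0.573 with estimated correlation). Among the antioxidant enzymes, Sod2 rose by 0.61 ± 0.1 and Gpx3 by 0.53 ± 0.11 (list adjusted p 0.00156, and 0.573 with estimated correlation). Smaller shifts passed in the nuclear encoded (median 0.11, adjusted p 0.000881) and the mitochondrially encoded (0.23, 0.0327) respiratory chain, in hypoxia and glycolysis (0.11, 0.0311) and, downwards, in smooth muscle and pericyte genes (−0.25, 0.0311). With estimated correlation the adjusted p of the nuclear encoded respiratory chain was 0.807 and that of the other 3 lists 0.573, and 28 to 42 of 100 splits of the controls gave a camera p as small for these 4 lists.

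With the correlation between genes estimated from the data, 0 of these 14 lists passed. Of 100 splits of the controls, a camera p as small came from 1 for the oocyte list, the real split, 3 for T and NK cell, 4 for antigen presentation, 5 for macrophage, 8 for luteal steroidogenesis, 9 for antioxidant enzymes, 16 for B and plasma cell and 26 for ovulation and cumulus expansion genes. By fry, which asks whether a list's genes move one way without comparing them with other genes, 5 lists passed: oocyte (adjusted p 0.00413), T and NK cell (0.0173), and macrophage, antigen presentation and luteal steroidogenesis (0.0381 each).

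The other lists did not pass camera. Follicular granulosa genes gave an adjusted p of 0.12, although Slc18a2, Esr2 (−1.1), Kctd14 (−0.49) and Ccnd2 (−0.42) were called lower and Cyp19a1 higher. The decrease of Ccnd2 was not seen with the clock gene score as covariate, where its change was 0.05. With that covariate the age comparison called 1104 genes, 523 higher and 581 lower in old ovaries, more than without it. Of the 151 named age genes, which include list members that were not called, 46 lost the call or turned in direction without one and 6 gained a call. Old and young controls differ in the score by 0.5 (exact permutation p 0.005). Senescence and secretory factors gave 0.177, with a median of −0.08 and a mean of 0.24 since Cdkn2a and Mmp12 stood apart. Adjusted p was 0.205 for erythroid and for endothelial genes, 0.267 for adipocyte genes, 0.297 for interferon response, 0.375 for surface epithelium and mesothelium, 0.393 for lymphatic endothelial, 0.62 for fatty acid oxidation and PPAR targets and for theca and interstitial, 0.643 for NRF2 targets, 0.835 for oviduct epithelium, 0.872 for aryl hydrocarbon receptor targets and 0.941 for immediate early and heat shock genes. The adipocyte genes, markers of another tissue, had a median of 1.67 with 7 of 9 higher, a larger shift than that of the immune lists; Plin4 (0.96) was called higher and Plin1 (−0.83) lower, and Fabp4 (1.46) and Car3 (1.67) were not called. It was 0.968 for neutrophil, unfolded protein response, ribosomal protein, and extracellular matrix and fibrosis genes. Median and mean had opposite signs for theca and interstitial (−0.06 and 0.02), NRF2 targets (0.01 and −0.01), extracellular matrix (0.02 and −0.02), neutrophil (−0.06 and 0.26), aryl hydrocarbon receptor (−0.03 and 0.03) and unfolded protein response (−0.03 and 0.02). Only 2 skeletal muscle genes were measured, too few for a test.

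The 2 animal batches differed in 4097 genes of the controls, 1637 higher and 2460 lower in batch 2, and the age effect itself differed between the batches in 4 genes. Age effects were therefore also fitted within a batch, which gave 253 genes in batch 1 and 83 in batch 2. The numbers of the control libraries did not pair them: same-numbered old and young libraries had correlations across genes of their deviations from −0.119 to 0.26.

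In batch 1, 19451 genes were tested for each of 14 compounds. The flavanone (±)-Naringenin called 33 genes, 19 higher and 14 lower than in old controls. Of these, Dbp rose by 1.19 ± 0.26 (adjusted p 0.0444) from 28.2 ± 4.121 to 64.23 ± 13.61 CPM, Per3 by 1.18 ± 0.2 (adjusted p 0.00875) and the anti-Müllerian hormone receptor gene Amhr2 by 0.87 ± 0.16 (adjusted p 0.0141). Ednrb changed by −1.3 ± 0.29, Ube2l6 by −1.01 and Cxadr by −1. The naringenin count was 0 without its replicate 2 or without old control 2, and 65 without its replicate 3. It was 0 against the 13 other compounds as reference, and 1 with the mitochondrial ribosomal RNA share or the clock gene score as covariate. Isofraxidin called 15 genes, 9 higher and 6 lower, among them Nfu1 (0.61), G6pc3 (0.58), Ubald1 (0.56), Zfp983 (−0.7) and Eid1 (−0.68); leaving out any 1 of its libraries or of the old controls left 0 to 4, and the 13 other compounds as reference left 0. The count was 5 with the mitochondrial ribosomal RNA share as covariate, with 3 of the 15 genes kept, and 1 with the clock gene score. The median fold of the 15 genes went from 0.58 (median SE 0.12) to 0.48 (0.11) and 0.54 (0.12). The folds thus shrank without a larger SE, more so with the first covariate. These losses do not decide on either measure as the cause, as isofraxidin libraries differ from the old controls in both. DESeq2 called 240 genes and edgeR with only the 6 libraries 3078.

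Linolenic acid called 8 genes, with Dbp at 1.41 ± 0.26 (adjusted p 0.0203), Per3 at 1.14, the interferon-inducible Ifi47 at 0.94 and, from the list of fatty acid oxidation, Acaa2 at 0.52 ± 0.1 (adjusted p 0.0368). Linoleic acid called 6 genes, with Per3 at 1.08 ± 0.21 (adjusted p 0.0331), the metallothionein gene Mt2 at 0.89 ± 0.16 (adjusted p 0.0145), Kdm4a at 0.47 and Ube2l6 at −1.21. Scopoletin called 6 genes, among them Stat3 (0.62 ± 0.12, adjusted p 0.0416), Atp23 (0.78) and Ubald1 (0.6). Columbianadin called 3 genes, with D16Ertd472e at −0.75, and ethyl palmitate 2, with Tnks1bp1 at −0.91 ± 0.16 (adjusted p 0.0197). Without 1 library the counts ran from 0 to 12 for linolenic acid, 0 to 6 for linoleic acid, 0 to 39 for scopoletin, 1 to 7 for columbianadin and 0 to 5 for ethyl palmitate. Against the 13 other compounds, linolenic acid and ethyl palmitate had 0 genes, linoleic acid 2, columbianadin 5 and scopoletin 45. With the mitochondrial ribosomal RNA share as covariate linolenic acid and scopoletin had 1 gene each, with the clock gene score linolenic acid, scopoletin and ethyl palmitate 1 each and linoleic acid 2, and with a GC offset linolenic acid 3 and scopoletin 1. With only the 6 libraries edgeR called 672 for linolenic acid, 23 for linoleic acid, 1 for scopoletin, 23 for columbianadin and 1280 for ethyl palmitate, and DESeq2 in the fit of the batch called 153, 17, 109, 109 and 50 in the same order. The predicted gene Gm15536 was called higher for 7 compounds of the batch (0.91 to 1.1), and the predicted gene Gm9130, at a low level, lower for 3. Of the genes within the naming limits, D16Ertd472e was called lower and Kdm4a higher for 4, Per3 for 3, and Mt2, Ube2l6, Nr1d2, Dbp, Thra, Ubald1 and Eid1 for 2.

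For the other 7 compounds of batch 1, edgeR called 0 genes. At an unadjusted p under 0.05, Scoparone had 3907 genes, Oleic acid 2569, 5,7-Dimethoxycoumarin 1235, Bergaptol 1170, Decursinol 680, 7-Methoxycoumarin 664 and Ethyl gallate 400, and DESeq2 called 652, 50, 2, 1, 1, 3 and 1 genes for them in the same order. Scoparone gave 2663 genes without its replicate 1, a count that rests on its replicates 2 and 3. These lie apart from replicate 1 and from the old controls in a trend with the mitochondrial ribosomal RNA share, given below. The F-test over all groups of the batch called 31 genes, 14 to 62 without 1 library and 6 with the clock gene score as covariate.

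In batch 2, 19533 genes were tested. Pyrogallol called 16 genes, 10 higher and 6 lower. Decreases included those of Cish, a target of cytokine and prolactin signalling, by −2.16 ± 0.45 (adjusted p 0.0467) from 85.03 ± 32.66 to 19 ± 6.301 CPM, and of the lipoprotein receptor gene Scarb1 by −1.36 ± 0.28 (adjusted p 0.0467). Prlr changed by −0.74 ± 0.14 (adjusted p 0.0425). Crabp2 (1.68 ± 0.3, adjusted p 0.0211), Ak4 (1.3) and Dok7 (1.09) were higher. Without old control 6 the count was 77, and it was 0 without pyrogallol replicate 1 or old control 5, or with only its 6 libraries in edgeR. It was 194 in DESeq2, 180 with the mitochondrial ribosomal RNA share as covariate and 162 without the benzoic and 4-hydroxybenzoic acid libraries. Isoferulic acid called 60 genes, 19 higher and 41 lower, with Slc45a3 at 1.21 ± 0.21 (adjusted p 0.00513), Pde8b at 1.06, Tmeff1 at 1.02, Tmem71 at −2.1, Runx3 at −1.89 and Maob at −1.79. Leaving out 1 library left 2 to 29 genes, and the 13 other compounds as reference left 0. The Isoferulic acid count was 223 in DESeq2, 124 with only its 6 libraries in edgeR and 128 with the clock gene score as covariate. Gallic acid called 3 genes, with Amhr2 at 0.78 ± 0.14 and Banp at 0.6, Aristolone 2 (Banp 0.62, S100a16 −0.7), and Protocatechuic acid 1, Rhoa, at −0.64 ± 0.11 (adjusted p 0.0152). These 3 counts were 0 without 1 or another library, while DESeq2 called 63, 8 and 49 genes in the same order. Gallic acid had 51 with the mitochondrial ribosomal RNA share as covariate and 1 with the clock gene score. Protocatechuic acid had 3 and 45 with these covariates.

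Of the compounds of batch 2 for which edgeR called 0 genes, Tetramethoxyflavanone7,3',4'5' had 1690 genes at an unadjusted p under 0.05, Vanillic acid 1392, Riboflavin 1297, Asiatic acid 1071, Naringenin chalcone 989, Rotundic acid 979 and Butein 925. DESeq2 called 40, 11, 4, 4, 1, 0 and 2 genes for them in the same order.

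Benzoic acid called 4757 genes, 2540 higher and 2217 lower, and 4-hydroxybenzoic acid 1126, 622 higher and 504 lower. Called in both were 574 of the higher genes, against 80.9 for independent sets, and 357 of the lower, against 57.2. Over 50 reassignments of the libraries, in which 2 groups also share 3 controls, the highest overlap was 0 in either direction. The covariance of their fold changes was 0.258, against a median of 0.116 and a highest of 0.2 in the reassignments, and the correlation 0.629, which lies within the reassigned values (median 0.53, highest 0.684). The overlap of independent sets leaves out the shared controls and the reassignments leave out the effects, and part of the excess may come from the old controls that both comparisons share. Ribosomal protein genes were higher with both, 41 of 50 called with benzoic acid (median 0.41, camera adjusted p 7.54e-17, 0.594 with estimated correlation) and 33 of 50 with 4-hydroxybenzoic acid (0.33, 3.24e-23, 0.44). Rpl13 rose by 0.73 and 0.67, and Rpl8 by 0.8 and 0.65. Oocyte genes were higher with both, with 11 of 25 called for each (camera adjusted p 2.31e-05 with benzoic and 1.65e-14 with 4-hydroxybenzoic acid, and 0.651 and 0.44 with estimated correlation). The oocyte list passed camera higher for 11 of the 14 compounds of the batch. Tcl1 rose by 1.35 with benzoic and 1.54 with 4-hydroxybenzoic acid, Zp1 by 1.54 and 1.63, and Padi6 by 0.97 and 1.05. The increases named by the rule with 4-hydroxybenzoic acid were the granulosa ligand gene Ihh (1.9 ± 0.35, adjusted p 0.00169), Apoa4 (1.66) and Obox2 (1.63). Apoa4, Obox2 and the oocyte list were lower with age, but old controls 4 to 6 serve in both comparisons, which opposes the 2 changes without any effect, so the opposition was not read further.

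Of 19 luteal genes, 6 were called lower and 2 higher with benzoic acid (camera adjusted p 0.0301, and 0.694 with estimated correlation). Lhcgr changed by −1.46 ± 0.3 from 883 to 321 CPM (adjusted p 0.00103), Prlr by −0.82 and Hsd3b1 by −0.68, while Por rose by 0.72. Of 23 cholesterol synthesis genes 4 were called lower (camera adjusted p 0.0234, and 0.841 with estimated correlation), among them Idi1 (−1.39) and Sc5d (−1.04). Of 17 genes of the unfolded protein response 7 were called, all higher (camera adjusted p 0.0312, and 0.8 with estimated correlation): Ddit3 by 2.06 ± 0.34 (adjusted p 0.000159), Hspa5 by 1.26, Herpud1 by 1.17 and Atf4 by 0.81. For Ddit3, replicate 3 stood at 333 CPM and the other two at 76.5 and 59.9, against 37.59 ± 2.81 in old controls. The same library led Ier3 (2.51; 312 CPM against 40 and 64.2) and Hmga1 (2.09; 31.1 against 13.4 and 11.5). Decreases by the naming rule were those of Hist2h2aa1 (−4.09), and of Ndufb4c and Rpl15-ps3, which stood at 0 CPM in 2 of 3 benzoic acid libraries each, so that their folds are not exact.

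With 4-hydroxybenzoic acid, Sox18 fell to the floor (0.755, 0 and 0.115 CPM against 3.16, 12.2 and 11.1 in old controls, adjusted p 0.000757), so that its fold is not exact. The other decreases named by the rule were Crtc2 (−3.32 ± 0.27, adjusted p 3.3e-10), from 15.01 ± 2.479 to 1.573 ± 1.225 CPM, and Sdhd (−2.94 ± 0.37, adjusted p 1.28e-05). Among the 491 genes called lower for which the 3′ end is known, 13.2% carry a TA repeat near the end, against 4.59% of the 17653 tested genes with a known end. The benzoic count was 1624 without its replicate 1 and 2970 without old control 5. The 4-hydroxybenzoic count was 130 without its replicate 1, 2024 without its replicate 2, 1912 without its replicate 3, 465 without old control 5 and 232 without old control 6. With only the 6 libraries of a comparison, edgeR called 0 genes for either, so that both counts rest on the spread shared by the 45 libraries. On the first component of batch 2, with 15.5% of the variance, benzoic acid replicates 1 to 3 stood at 100.97, 31.5 and 53.8. Those of 4-hydroxybenzoic acid stood at 85.65, 17.68 and 13.67, and old controls 4 to 6 at 6.03, −14.72 and −12.19. In both groups replicate 1 stood farthest out, so the shared spread may understate their error. The F-test over batch 2 called 3069 genes, and 25 when these 2 groups were left out.

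**Figure D2:**
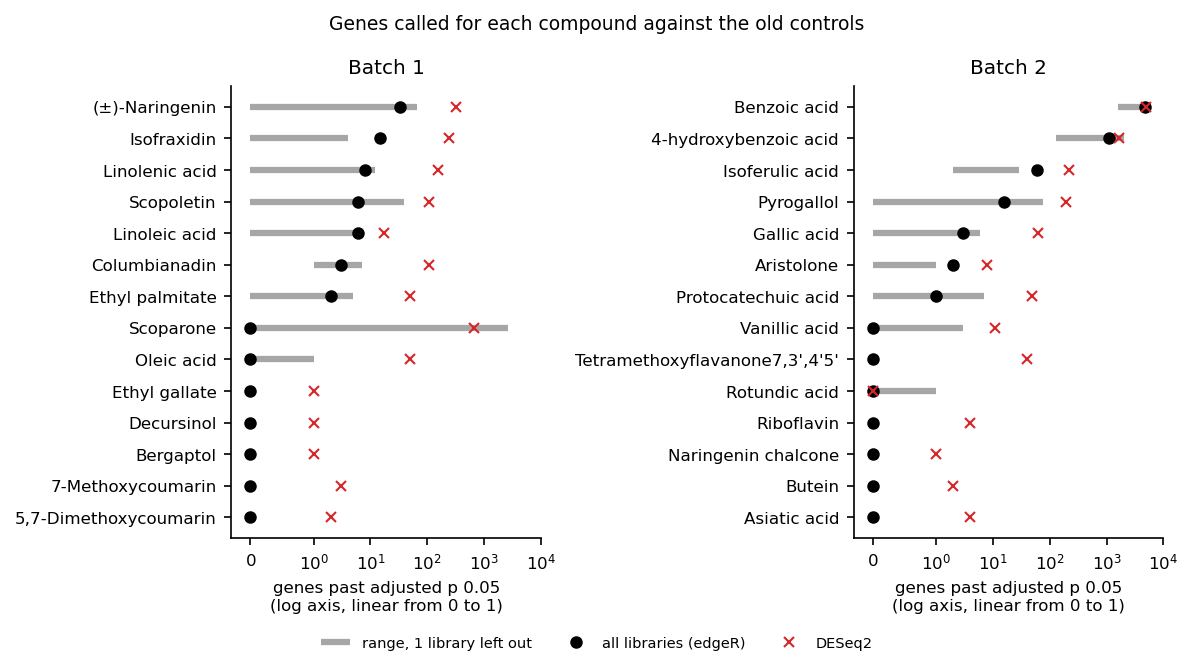
Genes past an adjusted p of 0.05 for each compound against the 3 old controls of its batch, by edgeR (circles), by DESeq2 (crosses) and as a range when 1 of the libraries compared is left out (grey bars), on an axis that is logarithmic above 1. Benzoic acid (4757 genes) and 4-hydroxybenzoic acid (1126) stand apart. Scoparone reaches 2663 genes without its replicate 1, a count that rests on its replicates 2 and 3.

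Across the batch 2 compounds, Banp was called for 6, Amhr2 for 5, Adap2 and the predicted gene Gm43618 for 4, and Cast, Pcyt1a, Shtn1, D16Ertd472e, Prlr and Dok7 for 3. Genes called for 2 or more compounds numbered 12 in batch 1, where reassigned groups gave at most 3, and 954 in batch 2, where they gave at most 7. Most of the 954 are the 574 higher and 357 lower genes that benzoic and 4-hydroxybenzoic acid share. Reassignment leaves out the effects, so its highest values do not measure how far real effects overlap. The mean covariance of fold changes across genes between 2 compounds was 0.173 in batch 1 (median 0.116 and highest 0.165 in 50 reassignments) and 0.137 in batch 2 (0.111 and 0.169). The mean correlation was 0.57 in batch 1, with 2 of 50 as large, and 0.523 in batch 2, with 19 of 50 as large. All comparisons of a batch share 3 old controls, which makes fold changes alike on its own, so part of any excess in shared genes may come from those controls.

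Among the 15 structural pairs within a batch, 3 had called genes, all with 4-hydroxybenzoic acid as a member. Protocatechuic acid, which has an added 3-hydroxy group, differed from it in 1115 genes, with Crtc2 3.57, mt-Tm −1.66 and Rapsn −1.62. Vanillic acid, with an added 3-methoxy group, differed from it in 1295 genes, with Crtc2 3.71, Rpl10-ps3 −1.55 and Eif4e1b −1.53. Sox18 was higher with either than with 4-hydroxybenzoic acid, where it is at the floor. Between 4-hydroxybenzoic and benzoic acid, which lacks the 4-hydroxy group, 58 genes differed, with Hist2h2aa1 4.72, Fbxl4 1.51, Srxn1 −3.01 and Cdkn1a −2.65. Srxn1 varied widely among the benzoic libraries, at 376.3 ± 552.2 CPM. Whether the structural difference is the cause was not tested for any of the 3 pairs. Without 1 library the 3 counts ran from 138 to 2273, 123 to 2524 and 7 to 2194. For the other 12 within-batch pairs and both pairs across batches edgeR called 0 genes, with 516 to 2128 at an unadjusted p under 0.05; DESeq2 was not run on pairs.

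Of 924 tests of a list and a compound, 267 passed at the preset correlation, 127 in batch 1 and 140 in batch 2, and 0 with estimated correlation, where the lowest adjusted p was 0.44. Adjusted within a batch, 125 and 146 passed, and 11 and 4 of 50 assignments of the libraries gave as many, with 186 and 214 in the highest other. All comparisons of a batch share 3 old controls, so lists shift alike for many compounds without any effect. At the preset correlation and in batch 1, the list of fatty acid oxidation and PPAR targets was higher than in old controls for 13 of 14 compounds (medians from 0.09 to 0.28 over all 14), as were the nuclear encoded respiratory chain (13), antigen presentation (13), ribosomal proteins (12) and interferon response (10). In batch 2, follicular granulosa genes were higher for 13 compounds (medians from 0.13 to 0.77), cell cycle genes for 13, ribosomal proteins for 12 and oocyte genes for 11, while luteal steroidogenesis was lower for 13 (medians from −0.57 to −0.21) and macrophage, cholesterol biosynthesis and interferon genes for 10 each. For single compounds these included cell cycle genes with Butein (median 0.45, adjusted p 1.27e-16, and 0.447 with estimated correlation), interferon response with Decursinol (0.54, 2.78e-12, and 0.44), cholesterol biosynthesis with Pyrogallol (−0.6, 3.76e-12, and 0.578) and luteal steroidogenesis with Pyrogallol (−0.45, 4.17e-10, and 0.44). NRF2 targets passed for Scopoletin alone (0.22, 0.00494, and 0.53 with estimated correlation), and aryl hydrocarbon receptor targets for no compound.

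The age score separated old from young controls by 1.45 in batch 1 and 1.75 in batch 2, with an exact permutation p of 0.1 in each, the smallest that 3 against 3 allows. No compound's score differed from the other aged libraries of its batch after adjustment over 28. Columbianadin was lower by −0.68 in 3 of 3 libraries (exact permutation p 0.0132, adjusted 0.205) and Pyrogallol by −0.6 in 3 of 3 (exact permutation p 0.0147, adjusted 0.205). Scoparone was higher by 0.57 (exact permutation p 0.0381, adjusted 0.355), with 1 of 3 libraries below the mean of the others. Against the old controls of the batch, all 14 compounds of batch 2 had a lower mean score, by −0.26 to −1.06, with Pyrogallol lowest, while those of batch 1 ran from −0.62 to 0.55. These differences share 3 old controls, and their exact permutation p cannot fall below 0.1. The variance between groups had a permutation p of 0.081 in batch 1 and 0.191 in batch 2. Of the 17 structural pairs, the 95% interval of the score difference excluded 0 for Ethyl gallate against Gallic acid (0.98, 0.1 to 1.86), which were in different batches. The intervals are not adjusted for the number of pairs, so that about 1 may exclude 0 by chance. Gallic acid differed from its old controls by −0.77 and Ethyl gallate by 0.21, so that most of the 0.98 lies in the distance of Gallic acid from the old controls of batch 2.

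**Figure D3:**
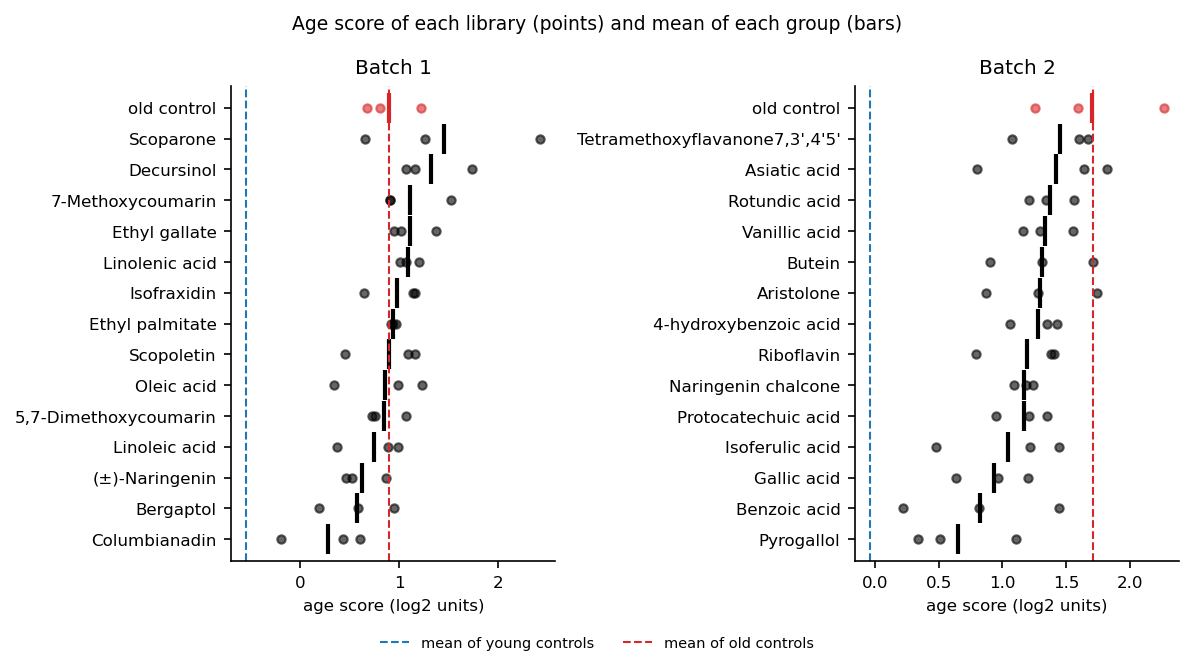
Age score of each aged library (points) and mean of each group (vertical bars), in log2 units, with the means of the old (red) and young controls (blue) of the same batch as dashed lines. Old controls averaged 0.9 in batch 1 and 1.71 in batch 2, and young controls −0.55 and −0.04.

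The clock gene score, which rises with Per3 and Dbp, differed among the groups of both batches (permutation p 0.00015 and 0.00251, adjusted 0.00075 and 0.00627 over 10 tests). Over the 14 compounds of a batch it followed the order in which the series lists them. In batch 1 rho was 0.93 and r 0.93 (permutation p 2e-05 and 1e-05, adjusted 0.0001). In batch 2 rho was 0.9 and r 0.91 (permutation p 2e-05 for each, adjusted 0.0001). Without the first and the last compound listed, r was 0.9 and 0.85. The score was listed after Per3, Dbp, Tef and Nr1d2 had been seen among the calls. In batch 1 these were called for compounds among the last 3 listed, so the batch 1 correlation is in part built in. The GC trend of the libraries also followed the listing order in batch 1 (rho 0.76, permutation p 0.00221, adjusted 0.00737). Its r there was 0.69 (permutation p 0.00669, adjusted 0.0223), and 0.53 without the first and the last compound. In batch 2 the GC trend passed by r (0.61, permutation p 0.0157, adjusted 0.0315) but not by rho (0.49, permutation p 0.0762, adjusted 0.109). The mitochondrial ribosomal RNA share followed the order in batch 2 (rho −0.69, permutation p 0.00772, adjusted 0.0193). In the clock gene score, old controls averaged −0.38 and −0.41, and young controls −0.92 and −0.87. The controls were left out of the correlations with the listing order. The series lists them after every compound, so their low scores do not follow that order. The compounds that called Per3 or Dbp, linoleic acid, linolenic acid and naringenin, are the last 3 listed in batch 1, and 4-hydroxybenzoic and benzoic acid the last 2 in batch 2.

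**Figure D4:**
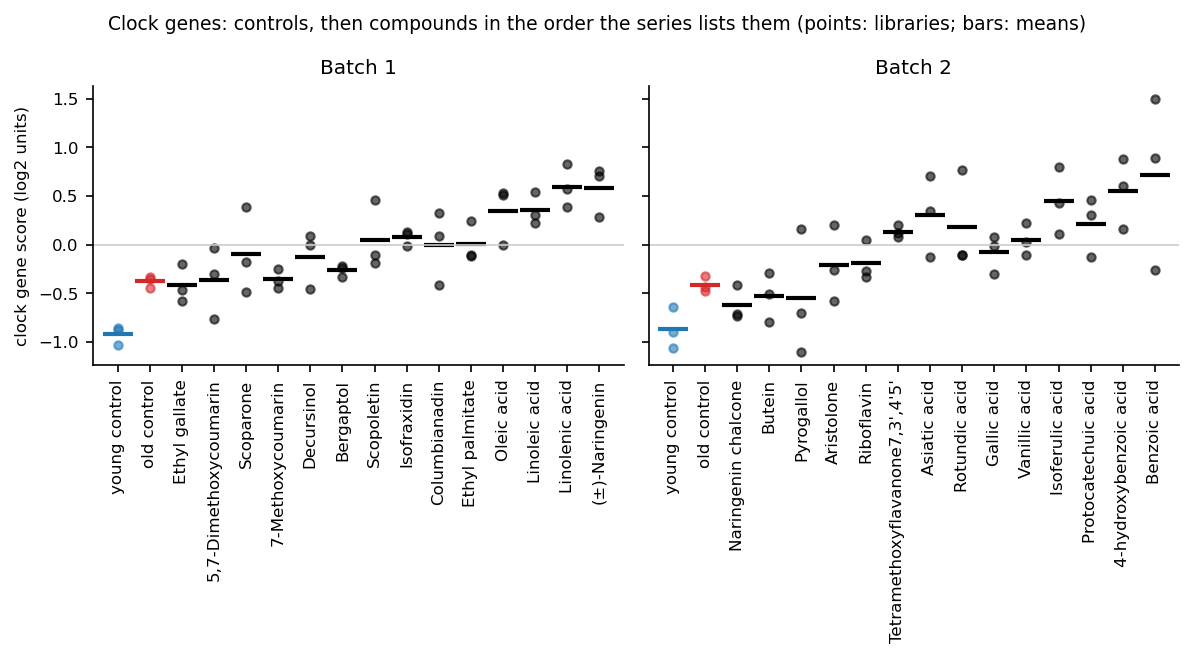
Clock gene score of each library (points) and mean of each group (bars), in log2 units centred within a batch, for the young and old controls and then the compounds in the order in which the series lists them. Naringenin, the last compound of batch 1, averaged 0.58 and benzoic acid, the last of batch 2, 0.71. The controls are drawn first, but the series lists them after all compounds.

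Other properties of the libraries moved with some groups. Benzoic and 4-hydroxybenzoic acid libraries had the highest mean GC trends of batch 2 (0.32 and 0.25, old controls −0.08). They also had the lowest mean shares of counts on processed pseudogenes (0.53% and 0.63%, old controls 0.66%). Mitochondrial ribosomal RNA made up 6.14% of counts (SD 0.94) in the old controls of batch 1. It made up 2.31% (SD 1.11) with naringenin, 2.34% (SD 0.33) with isofraxidin and 2.12% (SD 2.18) with Scoparone. These groups were not alone, as every compound of batch 1 had a lower mean share than the old controls. The means ran from 2.12% with Scoparone to 5.66% (SD 0.18) with Ethyl gallate. In batch 2 the old controls (3.01%, SD 0.88) also stood above every compound, of which Naringenin chalcone was highest (2.95%, SD 0.53). All comparisons of a batch with its old controls thus share a difference in this direction. Across the 45 aged libraries of batch 1, the first component, with 16.2% of the variance, had an absolute correlation of 0.99 with that share (0.99 without the 2 farthest libraries, rank correlation 0.98, permutation p 1e-05 for each correlation, the smallest these permutations can give). On that component Scoparone replicates 2 and 3 stood at 52.04 and 54.23 and its replicate 1 at −16.99. Old controls 1 to 3 stood at −22, −43.13 and −29.25. In batch 2 the absolute correlation was 0.22 (permutation p 0.153, and 0.19 without the 2 farthest). The rank correlation was 0.26 (permutation p 0.0807).

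**Figure D5:**
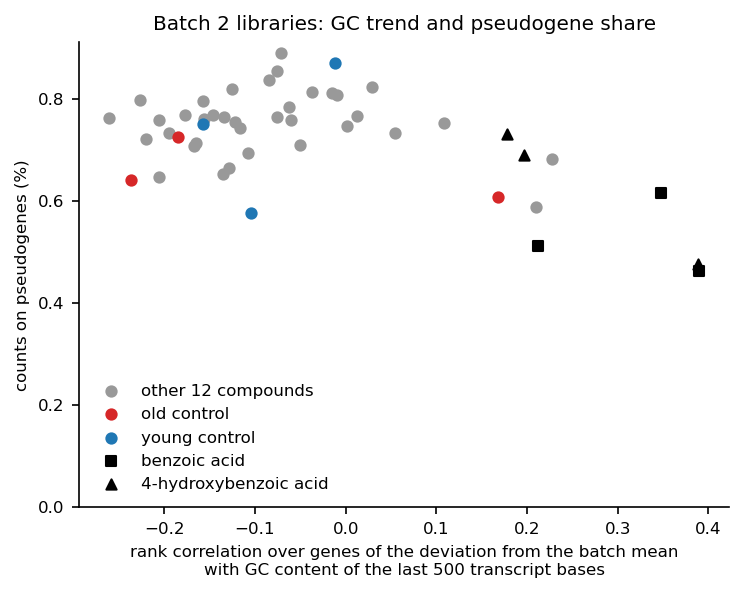
Share of counts on processed pseudogenes (%) against the GC trend of each batch 2 library. The trend is the rank correlation over genes of a library's deviation from the batch mean with GC content of the last 500 transcript bases. Benzoic acid (squares) and 4-hydroxybenzoic acid libraries (triangles) average 0.32 and 0.25 on the x axis.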

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

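All tests of explanations in this part were chosen after the results were seen; the tests of the interaction and the search for outlying libraries were not.

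In 3 of 52 groups of 6 control libraries tested, 1 library lay far from the others, and chance alone gives about 1 in 20. Acp5 in young control 4 stood at 1.7 log2 CPM, against 1.25 to 1.37 in the other 5 young controls (gap over range 0.739). Obox2 in old control 1 stood at 0.488, against 1.37 to 1.84 (0.653), and Mgat4c in old control 5 at 3.47, against 4.23 to 4.55 (0.701).

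The age effect differed between batches for 4 genes by the interaction test, each more strongly raised with age in batch 2: Cd28 by 4.58 (0.35 in batch 1, 4.93 in batch 2, adjusted p 0.0103), Inpp5j by 3.92 (−0.15 and 3.77, adjusted p 0.0465), Cdkn2b by 2.91 (−0.01 and 2.9, adjusted p 0.0103) and Klhl30 by 4.38 (−0.45 and 3.92, adjusted p 0.0465). Of 100 splits of the control libraries, 9 gave a count as large as the real 4, and the highest other gave 713, so chance cannot be excluded for this count, which ran from 0 to 9 without 1 library (given by library in the sensitivity part). The split with 713 genes places the 3 young controls of batch 1 with the 3 old controls of batch 2, so that its interaction is the age effect itself. No explanation was tested for these 4 genes.

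Clock genes followed the listing order of the compounds in both batches. In batch 1 this is in part built in, as some of the genes were seen called for the last compounds listed. A GC content trend is argued against, since the rank correlation with the order was still 0.78 or more after the GC trend of each library was removed. Time or order of collection along the list is a candidate explanation: genes of the opposite phase fell along the list, with a rank correlation of −0.79 in the weaker batch, as a shift of the clock needs. Effects of the compounds on the clock genes cannot be told apart from it, because each compound has 1 place in the list and similar structures are listed together; old minus young controls, without any compound, differed by 0.5 (exact permutation p 0.005 over 400 splits within batches), so that compounds are not the only source of clock differences. The labels give no collection times. The controls were left out of the correlations with the listing order. The series lists them after every compound, yet old controls averaged −0.38 and −0.41. The last compounds listed, naringenin and benzoic acid, averaged 0.58 and 0.71. Time or order of collection could thus explain the trend only if the controls were not collected last.

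Benzoic and 4-hydroxybenzoic acid called far more genes than the other compounds. As the whole cause, the GC content trend of the libraries is argued against by the calls left with a GC offset. Benzoic acid had 3496, with 2819 of them among the 4757 and a median fold of 0.65 before and 0.52 after. 4-hydroxybenzoic acid had 724, with 592 of them among its 1126 and median folds of 0.66 and 0.53. Without genes that have a TA repeat near the 3′ end, 4-hydroxybenzoic acid had 1009 calls. Of its called genes with a known end, 65 of 491 lower and 9 of 597 higher carry such a repeat. Removing them could take few calls, so this count does not decide on the loss of such transcripts. For the decreases with 4-hydroxybenzoic acid outside the 60 largest, 10.7% carry such a repeat (46 of 431, Fisher's exact p 5.41e-08, with genes that are not independent). That test did not match genes on GC content, and the GC trend of these libraries (0.25, old controls −0.08) goes with lower AT-rich ends. Within bins of GC content, genes with a repeat deviated from the others by −0.06 (SD 0.06), against −0.01 (SD 0.03) in old controls. The share thus does not decide whether loss of these transcripts contributed. With the clock score as covariate, benzoic acid had 2148 calls, 1931 of them among the 4757, and 4-hydroxybenzoic acid 297, 228 among its 1126, but the median folds went only from 0.65 to 0.55 (median SE 0.17 and 0.2) and from 0.66 to 0.57 (0.17 and 0.19), so these losses do not speak for time or order of collection, which stays open because both compounds are last in the list and the score is an imperfect stand-in for it. Effects of the 2 compounds stay open as well and were not tested apart from these.

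The count for naringenin in batch 1 went from 33 to 1 with the share of mitochondrial ribosomal RNA as covariate and to 1 with the clock score, a stand-in for time or order of collection along the list, and 0 of the 33 genes were still called in either. The median fold of the 33 genes went from 0.83 (median SE 0.16) to 0.65 (0.15) with the first and to 0.64 (0.2) with the second. The folds shrank with either and the SE grew with the second, so that the calls ended. The second test decides nothing, as Per3, Dbp, Tef and Nr1d2 are among the 33 genes and also part of the score, which was listed after they were seen. Neither explanation can be told apart from an effect of the compound, as its libraries differ from the old controls of the batch in both measures (mitochondrial ribosomal RNA 2.31% against 6.14%, clock score 0.58 against −0.38). Every compound of batch 1 had a lower mean share of mitochondrial ribosomal RNA than these controls, so that difference is not particular to naringenin.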

How the results depend on the processing

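The GC offset, the covariates for the mt-rRNA share and the clock score, the removal of genes with a TA repeat and the fits without the benzoic and 4-hydroxybenzoic acid libraries were chosen after seeing the data; the other alternatives were not. The age comparison gave 702 genes with DESeq2 size factors, 1104 with DESeq2, 726 with all 96 libraries in 1 fit and 626 with the replicate number as a block, against 743. The clock score as covariate gave 1104 as well. Where a count moved, the cause was not tested. Of the genes called without the filter, those that the filter removes were 86 in the age comparison and at most 79 for a compound, so most of any rise lies in genes that were already tested.

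Without the filter, edgeR called 1426 for the age comparison, 42 for the interaction, 3174 for the F-test of batch 1 and 5445 for the F-test of batch 2. In batch 1 they were 1080 for (±)-Naringenin, 230 for 5,7-Dimethoxycoumarin, 119 for 7-Methoxycoumarin, 218 for Bergaptol, 720 for Columbianadin, 105 for Decursinol, 87 for Ethyl gallate, 425 for Ethyl palmitate, 949 for Isofraxidin, 270 for Linoleic acid, 709 for Linolenic acid, 673 for Oleic acid, 1386 for Scoparone and 953 for Scopoletin. In batch 2 they were 1859 for 4-hydroxybenzoic acid, 381 for Aristolone, 263 for Asiatic acid, 217 for Butein, 682 for Gallic acid, 860 for Isoferulic acid, 322 for Naringenin chalcone, 419 for Protocatechuic acid, 914 for Pyrogallol, 418 for Riboflavin, 259 for Rotundic acid, 486 for Tetramethoxyflavanone7,3',4'5' and 426 for Vanillic acid. For pairs the counts were 421 for 5,7-Dimethoxycoumarin against Scoparone, 188 for 5,7-Dimethoxycoumarin against 7-Methoxycoumarin, 461 for Scoparone against 7-Methoxycoumarin, 448 for Scoparone against Scopoletin, 219 for Isofraxidin against Scopoletin, 85 for Linoleic acid against Oleic acid, 139 for Linolenic acid against Linoleic acid, 49 for Naringenin chalcone against Butein, 124 for Asiatic acid against Rotundic acid, 180 for Gallic acid against Pyrogallol, 158 for Gallic acid against Protocatechuic acid, 948 for 4-hydroxybenzoic acid against Benzoic acid, 90 for Vanillic acid against Protocatechuic acid, 419 for (±)-Naringenin against Naringenin chalcone and 225 for Ethyl gallate against Gallic acid.

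The DESeq2 Wald test called 319 for (±)-Naringenin, 2 for 5,7-Dimethoxycoumarin, 3 for 7-Methoxycoumarin, 1 for Bergaptol, 109 for Columbianadin, 1 for Decursinol, 1 for Ethyl gallate, 50 for Ethyl palmitate, 240 for Isofraxidin, 17 for Linoleic acid, 153 for Linolenic acid, 50 for Oleic acid, 652 for Scoparone and 109 for Scopoletin. The batch 2 counts were 8 for Aristolone, 4 for Asiatic acid, 2 for Butein, 63 for Gallic acid, 223 for Isoferulic acid, 1 for Naringenin chalcone, 49 for Protocatechuic acid, 194 for Pyrogallol, 4 for Riboflavin, 40 for Tetramethoxyflavanone7,3',4'5' and 11 for Vanillic acid. The DESeq2 likelihood ratio test called 677 for the F-test of batch 1 and 4685 for the F-test of batch 2. DESeq2 size factors gave 1 for Scopoletin.

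Against the 13 other compounds as reference, the counts were 0 for (±)-Naringenin, 12 for 5,7-Dimethoxycoumarin, 5 for Columbianadin, 1 for Decursinol, 0 for Ethyl palmitate, 0 for Isofraxidin, 2 for Linoleic acid, 0 for Linolenic acid, 22 for Scoparone and 45 for Scopoletin. Compounds of batch 2 had 2453 for 4-hydroxybenzoic acid, 0 for Aristolone, 1 for Asiatic acid, 7165 for Benzoic acid, 0 for Isoferulic acid, 0 for Protocatechuic acid, 1 for Riboflavin and 1 for Tetramethoxyflavanone7,3',4'5'. With adjustment over all 28 comparisons the counts were 57 for (±)-Naringenin, 1 for 5,7-Dimethoxycoumarin, 1 for Bergaptol, 30 for Columbianadin, 1 for Decursinol, 30 for Ethyl palmitate, 51 for Isofraxidin, 19 for Linoleic acid, 44 for Linolenic acid, 23 for Oleic acid, 12 for Scoparone and 39 for Scopoletin. For batch 2 this gave 286 for 4-hydroxybenzoic acid, 9 for Aristolone, 4 for Asiatic acid, 1289 for Benzoic acid, 2 for Butein, 22 for Gallic acid, 4 for Naringenin chalcone, 20 for Protocatechuic acid, 36 for Pyrogallol, 10 for Riboflavin, 8 for Rotundic acid, 21 for Tetramethoxyflavanone7,3',4'5' and 8 for Vanillic acid. With only the 6 libraries of a comparison, the counts were 20 for 7-Methoxycoumarin, 23 for Columbianadin, 9 for Ethyl gallate, 1280 for Ethyl palmitate, 3078 for Isofraxidin, 23 for Linoleic acid, 672 for Linolenic acid, 9 for Oleic acid and 1 for Scopoletin. In batch 2 they were 0 for 4-hydroxybenzoic acid, 40 for Aristolone, 0 for Benzoic acid, 124 for Isoferulic acid, 2 for Protocatechuic acid and 0 for Pyrogallol. The replicate number as a block gave 1 for Scopoletin. In batch 1 alone the count was 253 for the age comparison. In batch 2 alone it was 83 for the age comparison. With estimated correlation camera passed 0 for the compound lists of batch 1, 0 for the compound lists of batch 2 and 0 for the age lists. fry passed 5 for the age lists.

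A GC offset gave 18 for (±)-Naringenin, 8 for Isofraxidin, 3 for Linolenic acid, 1 for Scopoletin, 724 for 4-hydroxybenzoic acid, 1 for Aristolone and 760 for Vanillic acid against 4-hydroxybenzoic acid. The mt-rRNA share as covariate gave 48 for the F-test of batch 1. The batch 1 counts were 1 for (±)-Naringenin, 8 for Columbianadin, 5 for Isofraxidin, 1 for Linolenic acid and 1 for Scopoletin. The batch 2 counts were 742 for 4-hydroxybenzoic acid, 51 for Gallic acid, 3 for Protocatechuic acid and 180 for Pyrogallol. The clock score as covariate gave 6 for the F-test of batch 1 and 1786 for the F-test of batch 2. Compounds of batch 1 had 1 for (±)-Naringenin, 1 for Ethyl palmitate, 1 for Isofraxidin, 2 for Linoleic acid, 1 for Linolenic acid, 2 for Oleic acid and 1 for Scopoletin. Compounds of batch 2 had 297 for 4-hydroxybenzoic acid, 2148 for Benzoic acid, 1 for Gallic acid, 128 for Isoferulic acid, 45 for Protocatechuic acid and 1 for Tetramethoxyflavanone7,3',4'5'. For pairs the counts were 47 for Scoparone against Scopoletin, 1 for Linolenic acid against Linoleic acid, 726 for Protocatechuic acid against 4-hydroxybenzoic acid, 34 for 4-hydroxybenzoic acid against Benzoic acid and 777 for Vanillic acid against 4-hydroxybenzoic acid. Without the benzoic and 4-hydroxybenzoic acid libraries in the fit, the counts were 25 for the F-test of batch 2. For batch 2 this gave 7 for Aristolone, 2 for Asiatic acid, 97 for Gallic acid, 350 for Isoferulic acid, 64 for Protocatechuic acid, 162 for Pyrogallol, 13 for Riboflavin, 2 for Rotundic acid, 48 for Tetramethoxyflavanone7,3',4'5' and 19 for Vanillic acid. Without genes with a TA repeat the count was 59 for Isoferulic acid. The change of Ccnd2 with age went from −0.42 to 0.05 with the clock score as covariate, a score that itself differs with age. The cause was not tested.

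Counts with 1 replicate left out in turn, with the count over all libraries in parentheses, were as follows where they moved by over 1.5 times. The age comparison (743) ran from 398 to 723, with 398 without old control 1, 468 without old control 4, 453 without young control 1 and 437 without young control 5. The interaction (4) ran from 0 to 9, with 2 without old control 1 or old control 2 or old control 5 or young control 1 or young control 3, 0 without old control 3 or young control 2, 7 without old control 6 and 9 without young control 6. The F-test of batch 1 (31) ran from 14 to 62, with 62 without Scopoletin replicate 2 and 14 without Ethyl gallate replicate 3; without any 1 of the following it was at most 20, namely Ethyl gallate 1 or 2, 7-Methoxycoumarin 1 or 2 or 3, Decursinol 3, Scopoletin 1 or 3, Isofraxidin 2 or 3, Ethyl palmitate 1 or 2 or 3, Linoleic acid 2, Linolenic acid 1 or 2, (±)-Naringenin 1 or 2 and old control 1 or 2 or 3. The F-test of batch 2 (3069) ran from 1545 to 3444, with 1545 without Benzoic acid replicate 1.

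(±)-Naringenin (33) ran from 0 to 65, with 21 without its replicate 1, 0 without its replicate 2 or old control 2, 65 without its replicate 3, 15 without old control 1 and 2 without old control 3. Columbianadin (3) ran from 1 to 7, with 7 without its replicate 3 and 1 without old control 2 or old control 3. Ethyl palmitate (2) ran from 0 to 5, with 1 without its replicate 1 or its replicate 2, 0 without its replicate 3 or old control 2 and 5 without old control 3. Isofraxidin (15) ran from 0 to 4, with 1 without its replicate 1 or its replicate 3, 2 without its replicate 2 or old control 3, 4 without old control 1 and 0 without old control 2. Linoleic acid (6) ran from 0 to 6, with 2 without its replicate 1, 1 without its replicate 2 or old control 1 and 0 without old control 2. Linolenic acid (8) ran from 0 to 12, with 0 without its replicate 2 or its replicate 3 or old control 2 or old control 3. Oleic acid (0) ran from 0 to 1, with 1 without its replicate 3. Scoparone (0) ran from 0 to 2663, with 2663 without its replicate 1. Scopoletin (6) ran from 0 to 39, with 39 without its replicate 1, 22 without its replicate 2, 1 without old control 1 and 0 without old control 2 or old control 3. 4-hydroxybenzoic acid (1126) ran from 130 to 2024, with 130 without its replicate 1, 2024 without its replicate 2, 1912 without its replicate 3, 465 without old control 5 and 232 without old control 6. Aristolone (2) ran from 0 to 1, with 0 without its replicate 1 or its replicate 3 or old control 4 or old control 5 and 1 without its replicate 2 or old control 6. Benzoic acid (4757) ran from 1624 to 5803, with 1624 without its replicate 1 and 2970 without old control 5. Gallic acid (3) ran from 0 to 6, with 6 without its replicate 1 and 0 without its replicate 3 or old control 5 or old control 6. Isoferulic acid (60) ran from 2 to 29, with 2 without its replicate 1, 20 without its replicate 2, 22 without its replicate 3, 29 without old control 4, 16 without old control 5 and 10 without old control 6. Protocatechuic acid (1) ran from 0 to 7, with 0 without its replicate 1 or its replicate 2 or old control 4 and 7 without old control 5. Pyrogallol (16) ran from 0 to 77, with 0 without its replicate 1 or old control 5, 7 without its replicate 2, 2 without its replicate 3, 1 without old control 4 and 77 without old control 6. Rotundic acid (0) ran from 0 to 1, with 1 without its replicate 2. Vanillic acid (0) ran from 0 to 3, with 3 without old control 5.

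Scoparone against 7-Methoxycoumarin (0) ran from 0 to 528, with 528 without Scoparone replicate 1. Scoparone against Scopoletin (0) ran from 0 to 38, with 14 without Scoparone replicate 1 and 38 without Scopoletin replicate 2. Isofraxidin against Scopoletin (0) ran from 0 to 26, with 26 without Scopoletin replicate 2 and 2 without Scopoletin replicate 3. Linoleic acid against Oleic acid (0) ran from 0 to 1, with 1 without Oleic acid replicate 2. Protocatechuic acid against 4-hydroxybenzoic acid (1115) ran from 138 to 2273, with 357 without Protocatechuic acid replicate 1, 433 without Protocatechuic acid replicate 2, 546 without Protocatechuic acid replicate 3, 138 without 4-hydroxybenzoic acid replicate 1, 1907 without 4-hydroxybenzoic acid replicate 2 and 2273 without 4-hydroxybenzoic acid replicate 3. 4-hydroxybenzoic acid against Benzoic acid (58) ran from 7 to 2194, with 2194 without 4-hydroxybenzoic acid replicate 1, 7 without 4-hydroxybenzoic acid replicate 2, 9 without 4-hydroxybenzoic acid replicate 3, 219 without Benzoic acid replicate 1, 710 without Benzoic acid replicate 2 and 8 without Benzoic acid replicate 3. Vanillic acid against 4-hydroxybenzoic acid (1295) ran from 123 to 2524, with 498 without Vanillic acid replicate 1, 281 without Vanillic acid replicate 2, 845 without Vanillic acid replicate 3, 123 without 4-hydroxybenzoic acid replicate 1, 2324 without 4-hydroxybenzoic acid replicate 2 and 2524 without 4-hydroxybenzoic acid replicate 3. (±)-Naringenin against Naringenin chalcone (0) ran from 0 to 4, with 4 without old control 6. Ethyl gallate against Gallic acid (0) ran from 0 to 1, with 1 without Ethyl gallate replicate 3.

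The count of age lists stayed between 11 and 15 without 1 control library. For the age score, 0 compounds passed under the 4 alternatives and under the 84 scores without 1 library; the lowest adjusted p was 0.137. For the named genes and lists, 4110 values kept their direction and their side of the threshold. Another 136 kept their direction and gained a call, and 1061 lost the call or turned in direction without one. The remaining 1, the change of Ccnd2 given above, turned in sign. These rates differ by kind: with 1 library left out, named compound genes fell in the group that lost the call or turned in 233 values and kept their side in 163, and named age genes in 169 and 1603; against the 13 other compounds, named compound genes did so in 43 and 11. Simulated 1.5-fold changes were recovered for 31.3% of genes in a compound comparison of batch 1 and 34.3% in batch 2, so that changes of this size often went undetected.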

Other observations

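The tests with other splits in this part were all written down after the results were seen.

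For the age comparison, 1 of 100 splits of the 12 control libraries, the real one, gave as many as 743 genes, and the highest other gave 3, so chance can be excluded. The same holds for the batch difference, with 1 of 100 splits at 4097 genes and 1 in the highest other. For the 14 age lists it cannot be excluded: 15 of 100 splits gave as many, with 20 in the highest other.

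In batch 1, each real count was set against 50 assignments of the libraries to groups, with no allowance for the number of compounds. For the F-test (real 31, 1 of 50 as large, highest other 6) chance can be excluded at a share under 0.05. Naringenin (33, 1, 0), Isofraxidin (15, 1, 1), Linolenic acid (8, 1, 0), Linoleic acid (6, 1, 1) and Ethyl palmitate (2, 1, 1) had the same share, taken singly. For Scopoletin (6, 2, 6) and Columbianadin (3, 2, 4) another assignment gave as many or more. Each highest other is that in the compound's own place. A random group in the place of 7-Methoxycoumarin called 136 genes, more than any compound of the batch. Mixing the groups also changes the spread that the fit estimates. The assignments are too few to allow for the number of compounds, so chance is not excluded for a single compound.

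In batch 2, with 50 assignments, chance can be excluded for the F-test (real 3069, 1 of 50 as large, highest other 1524). It can be excluded for Benzoic acid (4757, 1, 15), which alone called more genes than every random group. 4-hydroxybenzoic acid (1126, 1, 42), Pyrogallol (16, 1, 2) and 3 pairs had the same share in their own places. The pairs are Protocatechuic against 4-hydroxybenzoic acid (1115, 1, 33), 4-hydroxybenzoic against Benzoic acid (58, 1, 12) and Vanillic against 4-hydroxybenzoic acid (1295, 1, 7). Elsewhere random groups called 18 (place of Rotundic acid), 47 (Asiatic acid) and 1018 genes (Tetramethoxyflavanone7,3',4'5'). Random pairs reached 1491 in the place of Gallic against Protocatechuic acid. Chance is thus not excluded for these compounds and pairs. For Isoferulic acid (60, 2, 4740) and Aristolone (2, 2, 271) another assignment gave far more. Chance cannot be excluded for Gallic acid (3, 3 of 50 as large, 320) or Protocatechuic acid (1, 4 of 50, 954). The assignments with 4740, 1524, 1018, 954, 320 and 271 genes point to a structure of the samples. The first 2 are the same assignment, which placed the 3 benzoic acid libraries in 1 group. Those with 1018, 954 and 320 placed 2 of them in 1 group. The one with 271 placed 1 of them beside 2 Pyrogallol libraries.

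For the compound lists, adjusted within a batch, 125 passed in batch 1, where 11 of 50 assignments gave as many and the highest other 186, and 146 in batch 2, where 4 of 50 did and the highest other gave 214. For neither count can chance be excluded.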
